A study of Clarias macrocephalus with 14 samples.

How the data were processed

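RNA was extracted from whole Clarias macrocephalus fry at 7 ages, depleted of ribosomal RNA and made into libraries with a NEBNext Ultra kit for Illumina sequencing, per the labels' protocols. That depletion step, unlike selection of poly(A) tails, also keeps transcripts without a tail. Sex was recorded as unknown. Libraries were grouped by the age in the labels, 2 per age.

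The values are expected counts, which the authors made from the reads with tools named in the submitters' processing notes and deposited with column totals that differ between libraries. The deposited table has 1 column per library, with 2.24 to 5.56% of values not whole numbers. The submitters' processing notes name CASAVA 1.9.1, FastQC, Trimmomatic 0.36, RSEM and DESeq2, without saying in which order or for which step they were used. RSEM estimates expected counts by sharing reads that match several transcripts among them. Per the file headers each line has a Trinity identifier, the form that the Trinity assembler writes, and a Gene ID. The assembly's version, how Gene IDs were assigned, any filter on the lines, whether counting used strand and a genome build are not given in the sources used here. The table has 172513 lines, called transcripts here, each with a different Trinity gene. They carry 25238 Gene IDs, and a single Gene ID can cover as many as 1912 transcripts. The Gene ID is a number for 166841 transcripts and a mix of letters and digits for the other 5672.

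The table does not pair its IDs with gene names and no reference was used. The 37 lists of genes and cell types fixed before the data were examined, from globins and hypoxia response to tissue markers, could therefore not be tested, nor could the rules for named genes that need symbols. The fallback rule fixed at the same time was used: for 24 against 3 dpf, name the 2 transcripts that rose and the 2 that fell with the largest absolute fitted log2 fold change and no others. They were taken among those with an adjusted p under 0.05, both libraries of an age above both of the other and a mean of at least 10 CPM at the higher age. In all, 7100 transcripts were eligible.

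Levels are given as CPM, the counts per 1e+06 TMM-scaled library counts. Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling). The filterByExpr filter with a minimum count of 10 kept 43551 transcripts of 18282 Gene IDs, which held 95.9 to 99% of each library's counts. All 14 libraries entered a single fit with age as the only term, so that the 7 ages shared an estimate of spread for each transcript. The tests were of any difference among the 7 ages, of the 6 consecutive steps and of 24 against 3 dpf, each with Benjamini-Hochberg adjustment within the comparison. Because both libraries of a group can be at 0, folds of named transcripts are given as bounds against a floor of 3 counts over the group, not as fitted values. Such floors cover counting error only.

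Each transcript past the test over the 7 ages was assigned the age with its highest mean log2 CPM (prior count 2). Stage-restricted sets were defined after seeing the data, as transcripts with at least 20 counts over the 2 libraries of each age in the set and fewer than 3 at every other age. The number of transcripts seen at equal depth was computed as an expectation under Poisson sampling of each library at the smallest library total.

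Depth and the spread between replicates both limit the precision. Totals were 2389483 and 2394686 counts at 3 dpf, 5509264 and 4502582 at 5 dpf, 3660103 and 2787143 at 13 dpf, 4784696 and 5282312 at 14 dpf, 6402796 and 8837320 at 16 dpf, 3395340 and 2933985 at 17 dpf and 1913945 and 1460853 at 24 dpf. TMM factors were 0.46 to 0.68 at 17 and 24 dpf and 1.08 to 1.37 at the other ages. Transcripts with at least 50 counts over the 2 libraries of an age entered a chi-square test of those counts, at unscaled totals. The test gave a mean per transcript for each age. It was 1.32 at 14 and 16 dpf, 2.34 at 3 dpf, 3.11 at 5 dpf, 3.17 at 17 dpf, 9.45 at 13 dpf and 16.6 at 24 dpf. Such means grow with depth and with a few high values. Where TMM factors differ within an age, as with 0.46 and 0.59 at 24 dpf, unscaled totals can also raise means and medians. Medians relative to counting noise were 1.86 at 13 dpf, 5.09 at 24 dpf and 1.22 to 2.07 at the other ages. Each pair differed by more than counting noise, and none was treated as a repeat deposit of the same library. The test cannot exclude technical repeats, since sharing reads among transcripts can also add to counting noise.

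The fit was tested on simulated counts drawn from the real library sizes and dispersions, with 200 transcripts changed in each of 5 draws. Changed transcripts were drawn from those with a mean of at least 5 CPM, so recovery at lower levels was not measured. Each transcript had a single dispersion at all ages, so the simulation cannot test the assumption that the ages share a spread. Each transcript's mean was taken over all 14 libraries, so no other transcript differed between ages. For 24 against 3 dpf, 18.8% of 2-fold and 71.4% of 4-fold changes were recovered among 36720 transcripts tested on average, and 3.8% of calls were false. For 13 against 5 dpf, 55.2% of 2-fold and 96% of 4-fold changes were recovered among 37113 tested on average, and 12.1% of calls were false, above the nominal 5%. In the data 46.9% of transcripts were called for 13 against 5 dpf. False and recovered shares depend on how many transcripts change, so the simulated shares are not those of the data. Counts of calls for 13 against 5 dpf may still hold more false calls than the threshold states.

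Alternatives were DESeq2 1.42.0 as test, its size factors or upper-quartile scaling in edgeR, limma-voom (limma 3.58.1), no low-count filter, at least 1 CPM in 4 libraries, an absolute log2 fold change of at least 1, adjustment over all comparisons together, the 20 highest transcripts left out, the 4 libraries of a comparison alone, the replicate number as a term, and each library left out in turn. Where leaving out a library left 1 at an age, that library was assumed to vary like those of the other ages. Alternatives added after seeing the data were counts summed per Gene ID, the stage-restricted sets left out, both together, and the libraries of 5 dpf, of 13 and 14 dpf or of 24 dpf left out of the fit.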

Results

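Transcript levels were profiled in whole fry of the broadhead catfish Clarias macrocephalus, an air-breathing freshwater fish, at 7 ages: 3, 5, 13, 14, 16, 17 and 24 days post fertilization (dpf). The series was made to follow expression over early development in a study of genes linked to air breathing. Each age had 2 libraries, 14 in all. Estimated read counts were given for 172513 transcripts of a de novo assembly under 25238 Gene IDs, without gene names, so the changes are described by transcript and Gene ID and no pathway or tissue is named. Library totals ranged from 1460853 counts in replicate 2 of 24 dpf to 8837320 in replicate 2 of 16 dpf. The labels do not say whether the replicates came from separate spawns, tanks or pools of fry, so all p-values measure only the spread between these samples, which may be technical.

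Over all tested transcripts, the 5 dpf libraries stood apart from every other age. On log2 CPM of the 43551 transcripts tested, the first principal component held 39.6% of the variance and placed the 5 dpf libraries at 303.8 and 330.1, against -154.3 to -3.6 for the other 12. The second held 24% and ran from 14 dpf (-168.9 and -167.8) to 24 dpf (168.8 and 175.9). Across transcripts, which are not independent replicates, Pearson's r between the 2 libraries of an age was 0.896 to 0.991. It was 0.466 to 0.665 between 5 dpf and any other age, and 0.694 to 0.909 between other ages. That gap in r closed with 2 stage-restricted sets of transcripts left out, which are described with the steps they belong to. There r between 5 dpf and other ages was 0.633 to 0.867, and 0.629 to 0.882 between the other ages. On Gene ID sums it was 0.665 to 0.842 and 0.732 to 0.92.

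**Figure D1:**
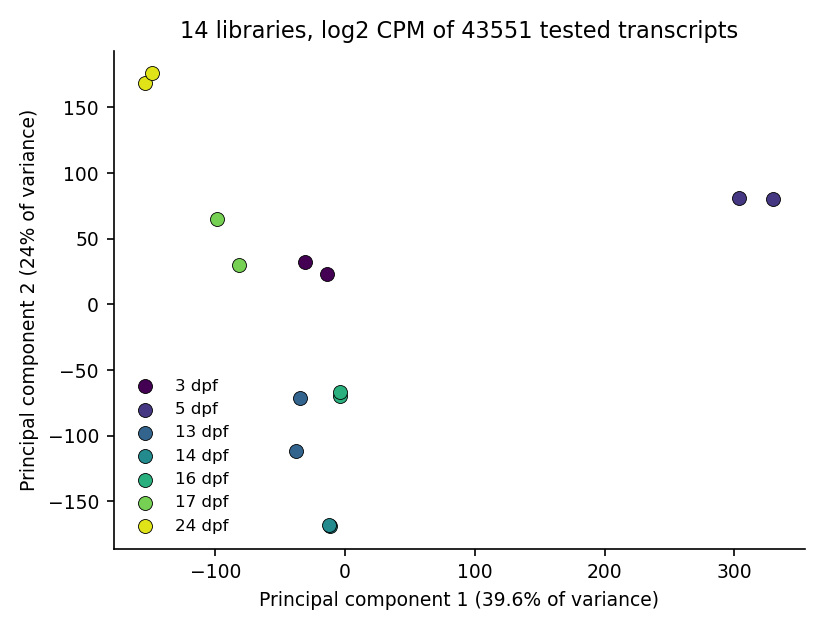
Scores of the 14 libraries on the first (x axis, 39.6% of variance) and second (y axis, 24%) principal components of log2 CPM over 43551 transcripts; each point is a library and its colour is the age. The 5 dpf libraries lie at 303.8 and 330.1 on the first component, and every other library lies below 0.

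Of the 43551 transcripts that passed the low-count filter, 36160 (83%), belonging to 16316 Gene IDs, differed among the 7 ages in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Without that filter 55371 of 167049 (33.1%) did. The highest mean level fell at 5 dpf for 10575 of them (29.2%), at 14 dpf for 6826 (18.9%), at 24 dpf for 5213 (14.4%), at 17 dpf for 4537 (12.5%), at 13 dpf for 3518 (9.7%), at 3 dpf for 3209 (8.9%) and at 16 dpf for 2282 (6.3%). When the stage-restricted sets were left out, 5410 transcripts peaked at 5 dpf and 6359 at 14 dpf, so 5 dpf no longer held the largest class. Steady courses were rare: 11 transcripts rose and 12 fell at every step, where a random order of the 7 stage means would give 7.2 of each. With counts summed per Gene ID, 16910 of 18840 Gene IDs (89.8%) changed, and peaks fell most often at 5 dpf (3542), 24 dpf (3214) and 14 dpf (2713).

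Between 3 and 5 dpf, 16823 transcripts (38.6% of those tested) changed, 11751 higher and 5072 lower at 5 dpf (edgeR, adjusted p under 0.05, 2 libraries against 2). A large part of the rise came from transcripts that were seen at 5 dpf and at no other age. This set held 7936 transcripts of 4501 Gene IDs, each with at least 20 counts over the 5 dpf libraries and fewer than 3 at each of the other 6 ages, and it took 8.4% ± 1.42 (SD, n = 2) of the counts at 5 dpf; its low level at the other ages follows from this definition. Summed over its members, the set still had 975 and 364 counts in replicates 1 and 2 of 3 dpf. In each library of 13 to 24 dpf it had 16 to 39 counts. The same definition applied to any other single age gave 3 to 62 transcripts. Of the 11751 transcripts that were higher at 5 dpf, 5345 belonged to the set, and these were all of its members that passed the low-count filter. Without the 5 dpf set and the smaller set of 13 and 14 dpf, 11521 of 37486 transcripts changed, 6453 higher (56%) and 5068 lower. Large fitted changes remained among these, with 499 at least 16-fold higher and 254 at least 16-fold lower. The share of changed transcripts that were higher, 69.9% with TMM scaling, was 52.8% with upper-quartile scaling. A filter of at least 1 CPM in 4 libraries, which removes transcripts seen in 2 libraries, gave 10566 changed transcripts.

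**Figure D2:**
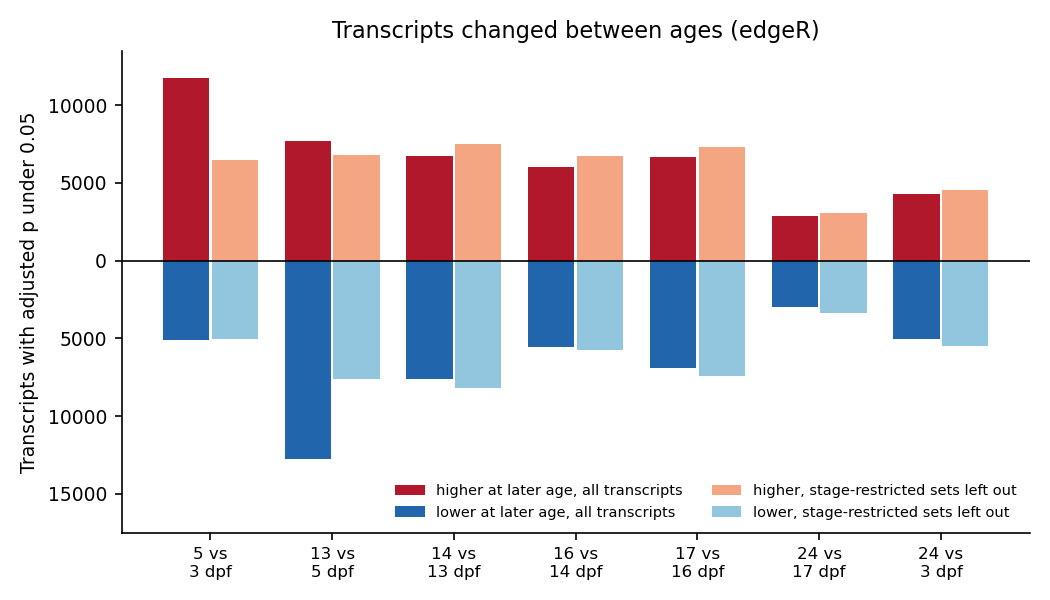
Number of transcripts (y axis) that were higher (upward bars) or lower (downward bars) at the later age in each comparison (x axis, dpf), by edgeR at an adjusted p under 0.05. Dark bars use all 43551 tested transcripts and light bars the 37486 tested when the stage-restricted sets were left out; the 11751 higher and 12735 lower transcripts on either side of 5 dpf become 6453 and 7583.

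Between 5 and 13 dpf, 20419 transcripts (46.9%) changed, 7684 higher and 12735 lower at 13 dpf. The 5345 tested members of the set seen at 5 dpf alone were among the 12735 lower, as the definition of the set requires of their counts. A second set was seen at 13 and 14 dpf and at no other age, with 805 transcripts of 631 Gene IDs, and the 791 of them that were tested were among those higher at 13 dpf, which again follows from how the set was defined. Without both sets, 14393 of 37486 transcripts changed, 6810 higher and 7583 lower. Among these, 708 were at least 16-fold higher and 619 at least 16-fold lower in the fit. The share of changed transcripts that were higher was 37.6% with TMM and 51.5% with upper-quartile scaling, so the side with more changes depended on the scaling.

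Between 13 and 14 dpf, a single day apart, 14330 transcripts (32.9%) changed, 6734 higher and 7596 lower at 14 dpf (edgeR, adjusted p under 0.05). The set seen at 13 and 14 dpf alone took 1.2% ± 0.0298 (SD, n = 2) of the counts at 14 dpf. At 13 dpf its share differed widely between the libraries, with 0.311% in replicate 1 (Wilson 95% interval 0.305 to 0.317) and 2.32% in replicate 2 (2.3 to 2.34); the intervals cover counting error only. Of this set, 44 transcripts were called higher and 22 lower at 14 dpf. With DESeq2's size factors in place of TMM, the log2 change of a transcript was higher by 0.13 in the median over transcripts, and there were 7944 higher and 6320 lower, so which direction prevailed was not settled.

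**Figure D3:**
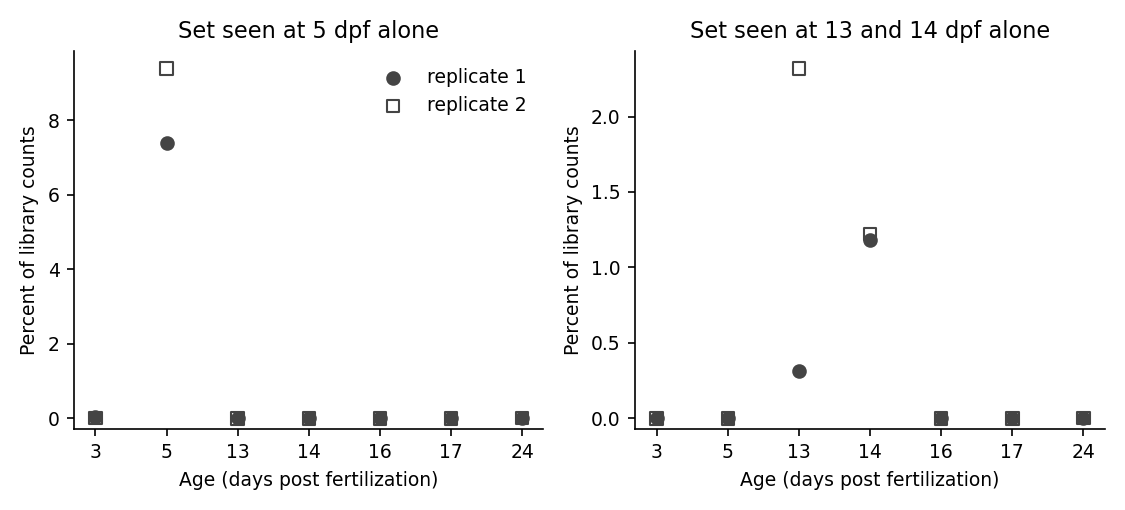
Percent of each library's counts (y axis) held by the transcripts seen at 5 dpf alone (left) and at 13 and 14 dpf alone (right), by age (x axis, dpf); filled circles are replicate 1 and open squares replicate 2. The left set holds 7.4% and 9.4% of counts at 5 dpf, and the right set 0.311% and 2.32% at 13 dpf and 1.18% and 1.22% at 14 dpf.

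Between 14 and 16 dpf, 11578 transcripts (26.6%) changed, 6028 higher and 5550 lower at 16 dpf. Of the 5550, 791 were the tested members of the 13 and 14 dpf set, which by its definition was near 0 at 16 dpf; without both sets 12469 of 37486 transcripts changed, 6752 higher and 5717 lower. Over Gene ID sums the libraries of 14 and 16 dpf had r of 0.916 to 0.92, the highest between any 2 ages; over transcripts r was 0.888 to 0.89, below the 0.909 reached by replicate 1 of 13 dpf with 16 dpf. The count differed with the libraries fitted: it was 6953 and 7065 without replicate 1 or 2 of 14 dpf, 7122 without replicate 2 of 16 dpf, and 19521 when the 4 libraries were fitted alone. With DESeq2's size factors the split turned to 5114 higher and 6579 lower.

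Between 16 and 17 dpf, again a single day, 13525 transcripts (31.1%) changed, 6647 higher and 6878 lower at 17 dpf (edgeR, adjusted p under 0.05). The prevailing direction depended on the method, with 7529 higher and 6104 lower under upper-quartile scaling, 13544 and 6315 by limma-voom, and 5744 and 9579 without the low-count filter. The make-up of the libraries changed at the same step. The transcript with the highest count at 17 dpf held 31.7% ± 1.53 (SD, n = 2) of all counts there, against 1.38% ± 0.0589 (SD, n = 2) at 16 dpf. The 20 highest transcripts of each library held 46.6% ± 0.501 (SD, n = 2) at 17 dpf and 11.1% ± 0.157 (SD, n = 2) at 16 dpf. CPM values of the remaining transcripts are therefore relative to scaling factors of 0.59 and 0.68 at 17 dpf, against 1.31 and 1.29 at 16 dpf. Leaving out the 20 transcripts with the highest totals kept the count of changed transcripts within 1.5 times.

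Between 17 and 24 dpf, 5838 transcripts (13.4%) changed, the fewest of the 6 consecutive steps by edgeR, with 2878 higher and 2960 lower at 24 dpf. Lower power at 24 dpf could also lower this count. In simulated counts 18.8% of 2-fold changes were recovered for 24 against 3 dpf and 55.2% for 13 against 5 dpf, and this step was not simulated. The transcript that led at 17 dpf also led at 24 dpf, with 19.7% ± 1.88 (SD, n = 2) of the counts. The libraries of 24 dpf detected fewer transcripts than those of any other age. At a fixed 1460853 counts per library, 34602 ± 272 (SD, n = 2) transcripts were expected to be seen at 24 dpf, 50978 ± 3930 (SD, n = 2) at 17 dpf and 55380 ± 125 (SD, n = 2) at 3 dpf. At unscaled totals the spread between replicates was also the widest. The mean chi-square per transcript was 16.6 at 24 dpf and 1.32 to 9.45 at the other ages. Its median relative to counting noise was 5.09 at 24 dpf and 1.22 to 2.07 at the other ages. The scaling factors of the 24 dpf libraries, 0.46 and 0.59, differed, which can raise both values. Only 4512 transcripts had the 50 counts required at 24 dpf, against 27590 at 16 dpf. Pearson's r between replicates was also lowest at 24 dpf, at 0.896. The number of changed transcripts was 3063 and 3750 without replicate 1 or 2 of 24 dpf and 15256 by limma-voom, where 14 against 13 dpf had the fewest (13595), and the share higher, 49.3% with TMM, was 60.3% with upper-quartile scaling and 59.5% with DESeq2's size factors, under which the log2 change of a transcript was higher by 0.12 in the median over transcripts.

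**Figure D4:**
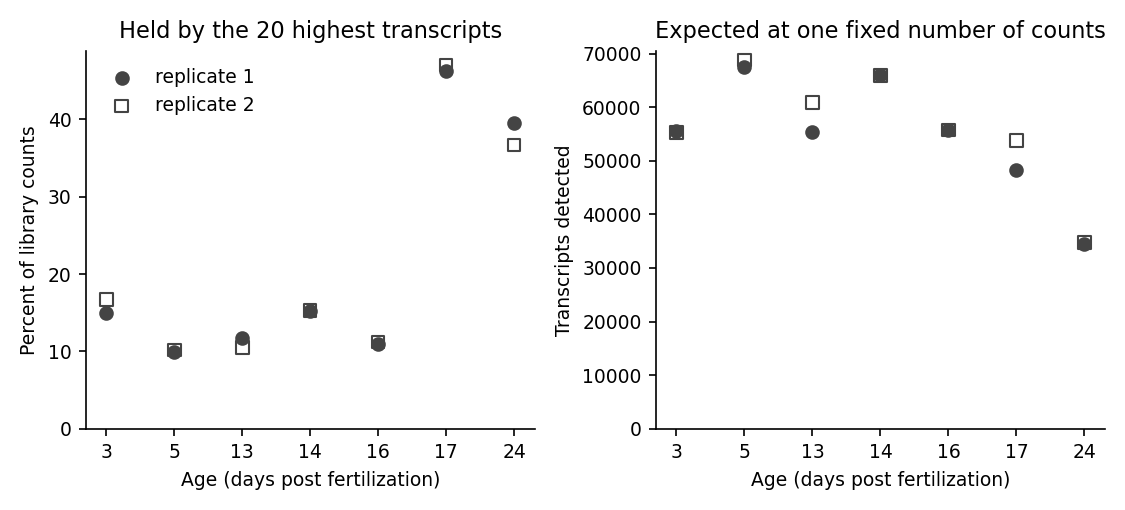
Left, percent of each library's counts (y axis) held by its 20 highest transcripts; right, transcripts expected to be detected at 1460853 counts (y axis), by age (x axis, dpf). Filled circles are replicate 1 and open squares replicate 2; at 24 dpf the libraries reach 34410 and 34794 transcripts, and those of 3 to 16 dpf reach 55292 or more.

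Over the whole span, from 3 to 24 dpf, 9369 transcripts (21.5%) of 6310 Gene IDs changed, 4308 higher and 5061 lower at 24 dpf. The largest fitted rises were in transcripts with 0 counts at 3 dpf. Ranking by fitted fold favours such transcripts, since the fit sets their fold without a measured lower level. TRINITY_DN152181_c1_g3_i1 (Gene ID 804884) had 110 CPM (95 counts) and 30.3 CPM (26 counts) in the 24 dpf libraries, a 24 dpf SD of 56.4 CPM (n = 2), and 0 counts in every library of 3 to 16 dpf. Against a floor of 3 counts over the 3 dpf group it was at least 139-fold higher at 24 dpf (edgeR quasi-likelihood test, adjusted p = 1.9e-06). With replicate 1 or 2 of 24 dpf left out the bound was 60.1-fold or 218-fold, and with replicate 1 or 2 of 3 dpf left out, which leaves fewer counts behind the floor, 67.3-fold or 72-fold. TRINITY_DN105211_c0_g1_i3 (Gene ID 100304562) had 89.2 and 27.9 CPM at 24 dpf and 0 counts in all other libraries, at least 116-fold higher (edgeR, adjusted p = 5.16e-06) with all libraries. Its bound was 55.4-fold or 177-fold without replicate 1 or 2 of 24 dpf, and 56.2-fold or 60.1-fold without replicate 1 or 2 of 3 dpf.

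The largest fitted falls were in transcripts that were abundant in the youngest fry and at 0 counts at 24 dpf, which the ranking favours in the same way. TRINITY_DN152563_c8_g3_i2 (Gene ID 108280774) had 602 and 328 CPM at 3 dpf (465 ± 194, SD, n = 2), 44.4 and 59 at 5 dpf, 0.433 and 1.63 at 13 dpf, 1.22 and 1.8 at 16 dpf and 5.08 and 2.56 at 17 dpf. At 14 dpf it was higher than at 13 or 16 dpf, with 46 and 64 counts against 2 and 6 at 13 dpf and 10 and 20 at 16 dpf. It was at least 267-fold lower at 24 than at 3 dpf (edgeR, adjusted p = 1.26e-09), and at least 133-fold or 134-fold without replicate 1 or 2 of 24 dpf, where the floor rests on fewer counts. TRINITY_DN86118_c1_g1_i1 (Gene ID 108266280) had 233 and 143 CPM at 3 dpf (188 ± 63.7, SD, n = 2), 64 and 47 counts at 5 dpf and 0.18 to 1.44 CPM from 13 to 17 dpf, and was at least 108-fold lower at 24 dpf (edgeR, adjusted p = 1.26e-09), or at least 53.7-fold or 54-fold without replicate 1 or 2 of 24 dpf. All 4 named transcripts stayed past the threshold, in the same direction, when each library of 3 or 24 dpf was left out. Because a Gene ID can cover several transcripts of the assembly, reads from near-identical copies could be divided among them, and these levels are those of the transcripts alone.

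The number of transcripts changed between 3 and 24 dpf was 5709 without replicate 1 of 24 dpf and 18050 by limma-voom. The share higher was 46% with TMM and 53.2% with DESeq2's size factors, and upper-quartile scaling gave 5364 higher and 3715 lower, so the prevailing direction turned with the scaling; under DESeq2's factors the log2 change of a transcript was higher by 0.11 in the median over transcripts.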

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

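The Gene ID sums, the left-out stage-restricted sets and the left-out ages were chosen after seeing the data; the other settings were fixed before the data were examined. Of 259 alternative values, 227 stayed within 1.5 times the reported count in either direction, and 32 did not. Counts of changed transcripts outside that range were as follows. Without a low-count filter 55371 of 167049 (33.1%) changed over the 7 ages, and with at least 1 CPM in 4 libraries 10566 changed from 3 to 5 dpf. By limma-voom 15256 changed from 17 to 24 dpf and 18050 from 3 to 24 dpf. From 14 to 16 dpf 6921 passed a log2 fold change of 1, and 19521 changed with the 4 libraries alone. The cause was not tested for the filters, limma-voom and the 4-library fit, while a fold limit can only lower a count.

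Counts summed per Gene ID gave 16910 changed over the 7 ages, 8535 for 5 against 3 dpf, 10095 for 13 against 5, 8873 for 14 against 13, 6217 for 16 against 14, 8722 for 17 against 16 and 6053 for 24 against 3. With the stage-restricted sets also left out these were 16602, 7654, 9251, 9132, 6504, 8859 and 6088. Fewer units, 18840 and 18532, were tested there, and the percent changed was higher than for transcripts in each of these comparisons. Fewer transcripts, 24751, had stage means spanning at least 2 log2 units. Of these, 1840 peaked at 3 dpf, 1767 at 13, 1441 at 16, 2736 at 17 and 3208 at 24 dpf. Peaks at 5 dpf (8575) and 14 dpf (5184) stayed within 1.5 times. The share peaking at 5 dpf was 34.6%, against 29.2% of all changed transcripts. At 14 dpf it was 20.9% against 18.9%, and at every other age the share was lower than among all changed transcripts. Without the restricted sets 5410 peaked at 5 dpf.

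Leaving out each library in turn gave 36081 to 42369 changed over the 7 ages, 11683 to 20554 for 5 against 3 dpf, 15789 to 24008 for 13 against 5, 9950 to 15547 for 14 against 13, 6953 to 14565 for 16 against 14, 9934 to 15638 for 17 against 16, 3063 to 7142 for 24 against 17 and 5709 to 10322 for 24 against 3. Counts moved by over 1.5 times for 16 against 14 dpf without replicate 1 (6953) or 2 (7065) of 14 dpf or replicate 2 of 16 dpf (7122), for 24 against 17 dpf without replicate 1 (3063) or 2 (3750) of 24 dpf, and for 24 against 3 dpf without replicate 1 of 24 dpf (5709).

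Replicate numbers did not pair the samples: over 21 pairs of ages the correlation of same-numbered deviations was -0.05 to 0.04. With the replicate block the counts were 34777 over the 7 ages and 15598, 19434, 13563, 11041, 12931, 5154 and 8662 for the 7 comparisons in order, all within 1.5 times. Not run for want of gene symbols were the gene lists, their estimated correlation, and sums per symbol. The 24 dpf libraries had the lowest totals of the 14, with 1460853 and 1913945 counts, and also the widest spread between replicates at unscaled totals.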

Other observations

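All tests in this part were chosen after the result was seen, except the one that leaves out the 20 highest transcripts at 24 dpf. The tests of an added source were also tightened, from a single matched draw to 20 with bootstrap intervals, after a first version came out narrowly in favour of that source at 5 dpf and narrowly against it at 13 dpf. The variant test was narrowed to Gene IDs with 1 other transcript past a count cutoff, after the version over all other transcripts past it.

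The ages did not line up in order of similarity. Libraries of 3 and 16 dpf had r of 0.883 to 0.891 across transcripts, close to 14 against 16 dpf (0.888 to 0.89). They lay above 17 against 24 dpf (0.825 to 0.852), where the 24 dpf replicates themselves reached only 0.896. The closeness to 14 against 16 dpf was absent on Gene ID sums, where 3 and 16 dpf had 0.848 to 0.861 and 14 and 16 dpf 0.916 to 0.92. On those sums 17 and 24 dpf had 0.815 to 0.842, still below 3 and 16 dpf. That closeness was also absent without the stage-restricted sets, with 0.814 to 0.827 and 0.876 to 0.882. There 17 and 24 dpf had 0.776 to 0.81, again below 3 and 16 dpf. The transcript with the highest count at 17 and 24 dpf was also the highest in both libraries of 3 and 13 dpf, with 5.71% ± 0.896 (SD, n = 2) and 3.71% ± 0.204 (SD, n = 2) of counts, and held 0.191% ± 0.0702 (SD, n = 2) at 5 dpf. It was singled out after its values were seen. The number of transcripts that together held 50% of the counts was 35 and 38 at 17 dpf, 59 and 86 at 24 dpf and 844 to 1624 at the other ages. A further 491 transcripts were seen at every age but 24 dpf, and 0 to 3 were missing at any other single age. With both stage-restricted sets left out, transcripts of a shared Gene ID followed related but not identical courses. Over 7588 Gene IDs with 2 or more remaining transcripts, a random pair had a median r of 0.58 across the 7 stage means (quartiles 0.15 and 0.83). Pairs of different Gene IDs had a median r of 0.06, and 18.8% of the same-ID pairs had a negative r.

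For the set of 7936 transcripts seen at 5 dpf alone, greater depth at 5 dpf was argued against, since 3479 transcripts met the definition with every age scaled to the smallest stage total, 3346 of them members of the set at full depth. A strain or allele variant that split the assembly was argued against as the whole cause: where a Gene ID had 1 other transcript, that partner should be lower at 5 dpf, but it was higher by 0.45 in median log2 change relative to other Gene IDs, and 3.5% of 1715 partners were lower by 1 log2 or more, against 9.4% of transcripts of other Gene IDs. Over all 10742 other transcripts of the set's Gene IDs past that cutoff the median was -0.08 against -0.06. Of these, 13.6% were lower by 1 log2 or more, so a variant behind a small part of the set is not excluded. RNA from an added source cannot be told apart from genes of the fry used at 5 dpf alone, and an effect of age stays open. The set's split between the libraries was offset by 0.43 log2 from matched transcripts, which an added source could give. Its overdispersion of 1.86 lay inside the 1.64 to 2.57 of 20 matched draws. Another transcript of their Gene ID was seen at all 6 other ages for 53.4% of members, near the 54.1% of matched transcripts. Matching by abundance was incomplete, with 3758 matched transcripts for the 7936 members here and 3296 for 3908 in the split, so the groups may differ in abundance.

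The 805 transcripts seen at 13 and 14 dpf alone differed as a set between the 13 dpf libraries, where replicate 2 had 5.61 times the counts of replicate 1 over the 331 members with at least 50 counts; depth was argued against, since 386 transcripts met the definition at equal stage totals, 382 of them members of the set at full depth. RNA from a single source mixed unequally into the 13 dpf libraries is a candidate explanation that the counts leave open: around their common split the members had an overdispersion of 6.04, where 20 matched draws gave 1.48 to 11.84 with a median of 2.54. In 14 of the 20 draws the set lay above the matched transcripts with an interval that left out 0, which goes against a single source, and in 6 the interval held 0. Between the 14 dpf libraries the set's overdispersion was 1.07, against 1.1 to 1.91 in matched draws. There the interval lay below 0 in 4 draws and held 0 in 16. Across transcripts their counts in replicate 2 of 13 dpf had a Spearman rho of 0.74 with those at 14 dpf (0.78 for transcripts seen at every age). Unequal progress through development among fry of an age stays open too, and was not tested.

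The low number of transcripts detected at 24 dpf was not explained by depth or by a few dominant transcripts. At a fixed 1460853 counts the higher 24 dpf library reached 34794 transcripts, against at least 55292 at 3 to 16 dpf, which argues against lower depth. With the 20 highest transcripts of each library left out and 925181 counts kept, it reached 34774 against at least 51129, which argues against those transcripts displacing the rest, whereas 17 dpf, with a similar dominance, rose to 50251 and 56122. A change in the fry with age, RNA quality and library preparation stay open and were not tested.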
